A study of Mus musculus with 6 samples.

How the data were processed

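Polyadenylated RNA from kidney glomeruli of 6 male mice aged 25 weeks was sequenced, 3 diabetic db/db mice and 3 non-diabetic db/m littermates. Per the labels' protocols, magnetic beads were perfused through the heart, the kidneys were minced and digested, and the bead-filled glomeruli were collected with a magnet. RNA was selected on oligo-dT, fragmented to a median of 150 bases and sequenced as paired ends for 76 cycles. Per the submitters' processing notes, the tools included FastQC, Trimmomatic, TopHat2 version 2.0.4 and Cufflinks, with the genome build mm9. Other versions and settings are not given in the sources used here.

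The deposited values are FPKM (fragments mapped to a transcript, relative to its length and to all fragments mapped), with the lower and upper limits that Cufflinks sets around each, per the file headers. Each file holds 30019 rows, and a row is 1 RefSeq transcript at 1 locus, paired with a gene symbol. The rows carry 29529 transcript IDs and 23221 symbols, and 252 IDs stand at more than 1 locus. FPKM of such IDs were summed. No read counts were used here, so the depth of each library is unknown. In its place, the median half-width of the Cufflinks interval was 12.5% to 14.1% of the value for rows between FPKM 1 and 10, and 5.61% to 6.23% above FPKM 10. That width covers estimation within 1 library and not the spread between mice. FPKM divides by transcript length, so rows of very short transcripts can take large values from few fragments. A share of the FPKM sum is therefore not a share of the fragments. How far such rows lower the values elsewhere in a library cannot be told without read counts. Overlapping isoforms and paralogs share reads that Cufflinks divides between rows, and a row at exactly 0 can be a failed division; rows of genes in general use, such as an isoform of the actin-capping gene Capzb, were also at 0. For such rows the values of each library are given and no fold change.

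The 302 IDs to which Cufflinks gave a status other than OK in any library were left out, 108 of them with a mean FPKM of at least 1. Among the rest, 11709 rows of 10777 symbols had a mean of at least 1 over the 6 libraries and were tested. Values were used as deposited, as log2(FPKM + 1), with limma 3.58.1 in R 4.3.3 (empirical Bayes with a variance trend, two-sided, no covariates) and Benjamini-Hochberg adjustment, at a threshold of 0.05. A fold change on that scale understates the change of low rows. Files were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The design had assumed 1 row per gene, while the files hold 1 row per transcript, so tests summed over symbols were added.

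Biotypes came from an NCBI RefSeq gene table of the assembly GRCm38.p6, used for names and biotypes only. By accession 28918 IDs matched, a further 550 by symbol or synonym, and 61 did not match. Coordinates are those of the files on mm9, counted from 1, and cover the span of the transcript. Of the tested rows 11300 were protein-coding and 298 noncoding, among them 208 long noncoding RNAs and 89 short noncoding RNAs.

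Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for naming genes had been fixed. Named are 9 genes whatever their values (of which Lepr, Tug1, Ppargc1a, Nphs1, Wt1, Malat1 and Neat1 are given), up to 10 rows per direction with the largest log2 fold change among rows past the threshold whose 3 db/db libraries all lay on 1 side of the 3 db/m libraries, the 5 noncoding rows per direction with the smallest p, and up to 4 members with the smallest p of each list described. Rows that share a symbol with another row are not named by fold change or as noncoding rows. Genes named outside this rule are said to be so, and a few that fall under it are not reported here. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, then with the correlation estimated from the data, and with fry. A listed symbol with several rows was represented by the row with the highest mean.

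The alternatives were pseudocounts of 0.1 and 0.01, a minimum mean of 0.1 or 5 or none, median-ratio scaling, quantile normalization, rescaling of each library to the same sum (TPM), 3 other variance models (no trend, robust, weights per library), the replicate number as a block, each library left out in turn, and rows of any status. Sums over the rows of a symbol, with and without median-ratio scaling, and leaving out db/m replicate 1 together with median-ratio scaling were added after seeing the data. The fit was tested on simulated data for the comparison of db/db with db/m, with the 11709 rows' own means and spreads and 200 rows changed. It recovered 7.41% of rows changed by 1 log2 unit, 63.8% of those changed by 2 and 77.0% of those changed by 3, and called 2 of 11509 unchanged rows. The changed rows were drawn from rows with a mean log2(FPKM + 1) above 2, so recovery of lower rows was not tested. Noise was drawn independently for each row and library. The simulation therefore held no library that stands apart and no correlation between genes, and its rates need not hold for the real libraries.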

Results

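The db/db mouse lacks the long, signalling form of the leptin receptor and becomes obese and type 2 diabetic, and its db/m littermates do not. Glomeruli, the filtering units of the kidney, were compared between 3 db/db and 3 db/m males at 25 weeks of age, in order to list noncoding RNA genes whose expression differs in diabetes. The unit was FPKM per RefSeq transcript, and depth is unknown. FPKM summed to between 210528 and 263655 per library. The labels do not say outright that each library came from its own mouse, although the series names 3 animals per group, so p-values measure the spread between these libraries.

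Tubule transcripts were abundant in these preparations. The median member of the proximal tubule list stood at FPKM 123, led by Kap (kidney androgen-regulated protein) at a mean of 3181, against 6.45 for podocyte, 7.51 for glomerular endothelial and 7.03 for mesangial and mural markers. The library of db/m replicate 1 stood apart. Short noncoding rows, mostly small nucleolar RNAs, took 70.7% of its FPKM sum, against 26.3% to 47.6% in the other 5 libraries, and protein-coding rows took 27.2%. The first principal component, with 52.6% of the variance, placed it at 82.6 and the others between -34.5 and -1.89. No pair of libraries shared an identical value above 0 in any tested row. The median log2 fold change of all tested rows was 0.29 as deposited, 0.10 without db/m 1 and -0.0032 after median-ratio scaling, so medians of gene lists are given relative to that of all rows.

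**Figure D1:**
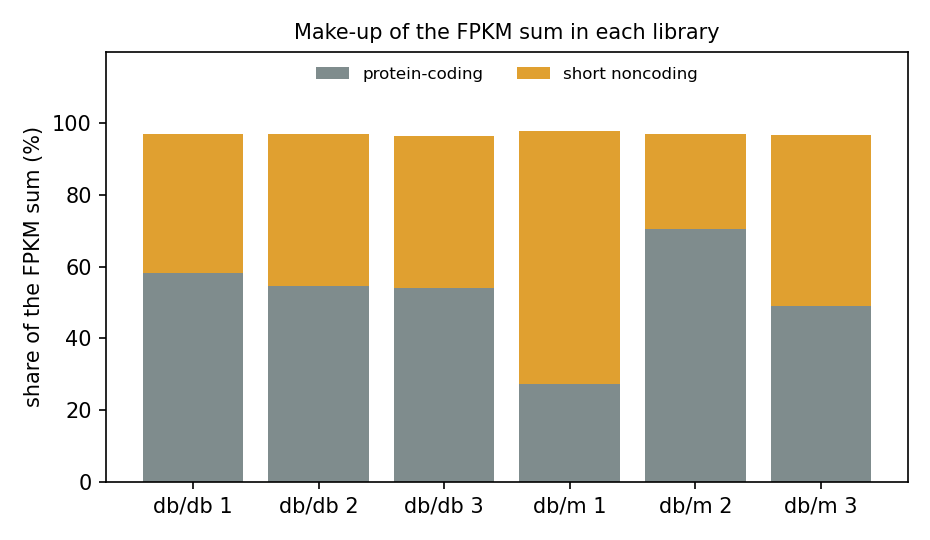
Stacked bars give, for each of the 6 libraries, the percentage of the FPKM sum in protein-coding rows (grey) and in short noncoding rows (orange). In db/m 1 short noncoding rows hold 70.7% of the sum, more than in any other library.

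Lepr, the gene whose db change defines the groups, was low in all libraries. Its main row (NM_001122899, chromosome 4, 101390012 to 101486272 on mm9) had an FPKM of 0.624 ± 0.047 (SD, n = 3) in db/db and 0.865 ± 0.043 (SD, n = 3) in db/m, under the minimum for testing, a second row was at 0 in all 6 libraries, and a further row (NM_146146) was at 0.164 in db/db 3 and at 0 in the other 5. The db change alters splicing, so this level says little about the labels.

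The 10 named genes that were higher in db/db had low or no signal in db/m. Ugt1a10, a UDP-glucuronosyltransferase that conjugates drugs and steroids, was listed at 41.6, 37.8 and 21.2 in db/db and at 0 in all 3 db/m libraries (NM_201641, chromosome 1, 89951986 to 90116577; adjusted p = 0.00129, limma). Gsta2, a glutathione S-transferase, rose from 2.06 ± 0.70 in db/m to 51.2 ± 30.5 in db/db (SD, n = 3 each), a ratio of 24.9 (NM_008182, chromosome 9, 78178827 to 78194952; log2 fold change 3.97, SE 0.43, adjusted p = 0.0184). Its neighbour Gm10639 rose from 0.446 ± 0.166 to 19.5 ± 8.8 (chromosome 9, 78137735 to 78153332; adjusted p = 0.00531). Bhmt, which remethylates homocysteine with betaine, rose from 0.411 ± 0.074 to 13.99 ± 5.50 (NM_016668, chromosome 13, 94386846 to 94407713; log2 fold change 3.35, SE 0.26, adjusted p = 0.00531). Gc, the vitamin D-binding protein, rose from 1.23 ± 0.16 to 14.2 ± 5.0 (chromosome 5, 89846536 to 89886923; adjusted p = 0.0184).

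Ftcd, an enzyme of histidine and folate metabolism, was 5.18 times higher in db/db, the aldo-keto reductase Akr1c13 5.96 times and Kynu, the kynureninase of tryptophan breakdown, 12.3 times. Their adjusted p were 0.0194, 0.0345 and 0.0498. Gm9781 was listed at 6.17, 3.65 and 2.58 in db/db and at 0 in each db/m library (adjusted p = 0.0279). Several of these rows share sequence or a locus with others and are uncertain. The Ugt1a genes share their last exons. At the same locus Ugt1a7c stood at 74.8 to 152 in db/db and 30.9 to 120 in db/m, Ugt1a2 at 0, 51.9 and 28.8 in db/db and 0 in each db/m library, and Ugt1a6b at 13.8 in db/m 1 and 0 in the others, so the 0s of Ugt1a10 can reflect how reads were divided. Gsta2 and Gm10639 belong to a cluster of similar genes, and Akr1c13 has close paralogs. Gm9781 covers the locus of Eif3j, whose own row was left out for its status. That Eif3j row went the other way, at 2.66, 3.74 and 4.05 in db/db and 4.92, 7.95 and 6.64 in db/m. The 0s of Gm9781 in db/m can therefore also reflect how reads were divided.

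Of the 5 named genes that were lower in db/db, 3 encode transporters of organic anions or related to them. Slco1a1 fell from 46.4 ± 24.6 in db/m to 1.43 ± 1.15 in db/db (SD, n = 3 each), a ratio of 32.6 (NM_013797, chromosome 6, 141855802 to 141895483; log2 fold change -4.26, SE 0.47, adjusted p = 0.0192). The neighbouring paralogs Slc22a30 and Slc22a28 fell from 39.9 ± 7.5 to 7.60 ± 1.34 and from 33.5 ± 4.5 to 7.10 ± 1.19 (chromosome 19, 8410113 to 8479595 and 8136699 to 8206472; adjusted p = 0.0498 for both), and reads can be split between them. Alox15, the arachidonate 15-lipoxygenase, fell from 5.10 ± 2.42 to 0.214 ± 0.020 (chromosome 11, 70157649 to 70165533; adjusted p = 0.0291). The kinase gene Map3k15 was listed at 3.49, 3.61 and 3.55 in db/m and at 0 in each db/db library (chromosome X, 156426365 to 156561283; adjusted p = 0.00531). Its row overlaps that of Pdha1.

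**Figure D2:**
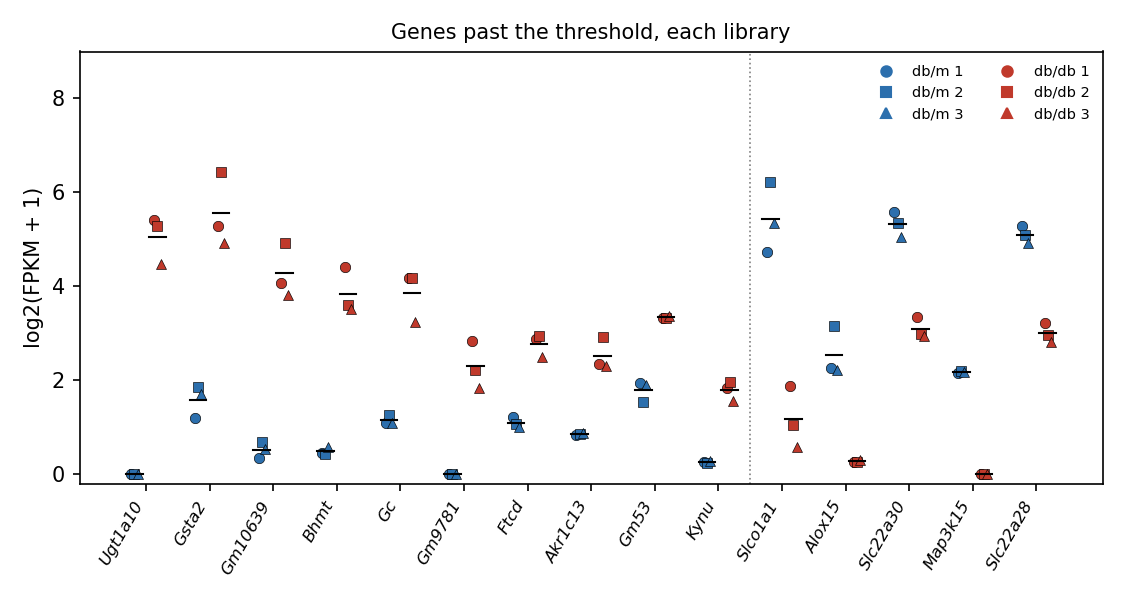
Each point is 1 library (blue db/m, red db/db, marker shape the replicate number), the vertical axis is log2(FPKM + 1) and black lines are group means. The 10 genes left of the dotted line were higher and the 5 to its right lower in db/db, with no overlap between the groups. Ugt1a10 and Gm9781 are at 0 in all db/m libraries and Map3k15 in all db/db libraries.

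In all, 22 of 11709 rows passed, 14 higher and 8 lower, and 876 had an unadjusted p under 0.05, 780 higher and 96 lower. With median-ratio scaling 23 rows passed, 10 higher and 13 lower, 15 of them shared with the 22, and 343 higher and 419 lower rows had an unadjusted p under 0.05. Of the 22 rows 15 are the named genes, and the other 7, of Dab2, Gprc5c, Hiatl1, Bri3, Mfge8, Taf9 and Capzb, were rows of single isoforms at 0 in all libraries of 1 group, named here after their values were seen. None of these 7 genes passed with its rows summed (adjusted p 0.551 to 0.785). Leaving out 1 library changed the count to 10 (db/db 1), 13 (db/db 2), 21 (db/db 3), 8 (db/m 1), 28 (db/m 2) or 4 (db/m 3). Of the 15 named genes, in the same order, 5, 5, 8, 2 (Ugt1a10 and Map3k15), 8 and 1 (Ugt1a10) passed, and 9 passed with median-ratio scaling, where Slc22a28, Slc22a30, Akr1c13, Ftcd, Kynu and Gm53 did not (adjusted p 0.0509 to 0.264). Ugt1a10 passed in all 22 alternatives, and all 15 kept their sign in every alternative that tested them. The naming rule chose genes without overlap between the groups, so only another scaling could have turned a sign.

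Of 298 noncoding rows, 1 passed. Gm53, a long noncoding RNA, rose from 2.50 ± 0.52 in db/m to 9.16 ± 0.17 in db/db (SD, n = 3 each; NR_037977, chromosome 11, 96112974 to 96125798; log2 fold change 1.55, SE 0.20, adjusted p = 0.0377, and 0.0182 adjusted over the list alone, where it was again the 1 row to pass). With median-ratio scaling its adjusted p was 0.264, and it passed in none of the 6 fits with a library left out (0.0548 to 0.249, limma) and in 4 of all 22 alternatives (0.000996 to 0.264). A further 20 noncoding rows had an unadjusted p under 0.05, which with Gm53 made 17 higher and 4 lower.

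Among noncoding rows that did not pass, those with the smallest p were, on the higher side, 2610306M01Rik (2.71 ± 0.37 in db/db, 1.32 ± 0.19 in db/m), Gm10787 (3.24 ± 0.92, 1.28 ± 0.62), C730027H18Rik (2.98 ± 0.14, 1.65 ± 0.38) and 1700052K11Rik (2.02 ± 0.34, 0.943 ± 0.320), with adjusted p from 0.445 to 0.568. On the lower side they were Snhg11, a small nucleolar RNA host gene (5.39 ± 0.69 in db/db, 11.3 ± 1.7 in db/m, adjusted p = 0.399), LOC626693 (2.43 ± 1.10, 6.75 ± 3.94), BC024386 (11.8 ± 1.2, 18.8 ± 4.3), Mir697 and Snord23, the last 4 with an adjusted p of 0.595. Mir697 was listed at 20.7, 22.7 and 0 in db/m and at 0 in db/db, and without db/m 3 it passed (adjusted p = 0.00155, over all alternatives up to 0.905). Snord23 was listed at 116, 122 and 160 in db/m and at 76.0, 0 and 64.3 in db/db. Of the long noncoding RNAs fixed by name, Neat1 stood at 126 ± 14 and 124 ± 10 and the longer Tug1 row at 11.3 ± 0.3 and 9.45 ± 1.83 in db/db and db/m (adjusted p 0.983 and 0.618); the sign of both turned with median-ratio scaling. The shorter Tug1 row went the other way as deposited, at 3.03 ± 0.60 in db/db and 3.33 ± 0.66 in db/m (adjusted p = 0.774, limma). Malat1 was not tested. It was listed at 0 in db/m 1, where Cufflinks marked it as having too much data, and between 1253 and 1744 in the other 5 libraries.

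None of the 24 podocyte, 19 endothelial and 14 mesangial and mural markers passed the test, over all rows or adjusted over the list alone, and 0 of them had an unadjusted p under 0.05 (limma). Nphs1 (nephrin) measured 10.1 ± 1.5 in db/db and 7.14 ± 4.15 in db/m and Wt1 3.65 ± 1.81 and 2.83 ± 2.56 (SD, n = 3 each; adjusted p from 0.595 to 0.654, limma). Of 17 loop, distal tubule and collecting duct markers none passed over all rows and 3 adjusted over the list alone, all higher in db/db: Calb1 (calbindin, 30.7 ± 2.9 against 10.7 ± 4.2), Atp6v1g3 (3.14 ± 0.42 against 1.52 ± 0.24) and Trpm6 (3.75 ± 0.39 against 1.94 ± 0.36). With median-ratio scaling only Calb1 of these passed over the list alone; without db/m 1 the list alone gave 3, without db/m 2 8 and without any of the other 4 libraries 0. Haemoglobin rows varied widely within each group: Hba-a1 ranged from 0.490 in db/m 1 to 1306 in db/db 2 and 984 in db/m 2. The red cell list had a median 1.19 above that of all rows while camera gave it the direction down (adjusted p = 0.811), and for the podocyte, endothelial and mesangial lists the median was -0.011, -0.015 and 0.38 from that of all rows (adjusted p 0.222, 0.334 and 0.141 by camera). These 3 results turn on single libraries at the preset correlation of 0.01 only. The podocyte and endothelial lists passed as lower without db/m 1 (camera adjusted p 0.00274 and 0.00224; adjusted p = 0.898 with an estimated correlation) and without db/db 3 (0.0119 and 0.00696; adjusted p = 0.997 with an estimated correlation). The mesangial list passed as higher without db/db 2 (9.51e-05), without db/m 3 (0.0026) and with median-ratio scaling (0.012) or quantile normalization (0.0162), and each call was lost, with adjusted p = 0.941, 0.93, 0.912 and 0.862 with an estimated correlation. By fry, which asks whether a list moved from 0, all 3 had the direction up as deposited (adjusted p 0.798, 0.803 and 0.683).

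Over the 28 lists tested, camera called 8 as deposited, with 2 higher and 6 lower relative to other rows. The balance turned with the scaling and with 1 library: 6 higher and 4 lower with median-ratio scaling, 5 and 5 with quantile normalization, and 6 and 2 without db/m 2. None held with an estimated correlation (lowest adjusted p = 0.992 as deposited, and 0.912, 0.862 and 0.882 in these 3 settings) and none passed with fry (lowest adjusted p = 0.0796, with 2 lists at an unadjusted p under 0.05). No member of any list passed over all rows (limma), and 45 of 526 entries had an unadjusted p under 0.05. The lymphoid, mitochondrial DNA and adipocyte lists had 0, 0 and 4 tested members and were not tested.

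The circadian clock list lay 0.46 above the median of all rows (camera adjusted p = 0.0017; adjusted p = 0.992 with an estimated correlation). Adjusted over the list alone, 6 of 13 members passed, all higher in db/db, among them Dbp (12.9 ± 3.2 against 3.34 ± 2.68 in db/m), Cry2 (3.07 ± 0.53 against 1.40 ± 0.39), Hlf (8.81 ± 0.73 against 3.89 ± 1.71), Gm129 and Per2 (SD, n = 3 each). With median-ratio scaling none of the 13 passed over the list alone and the list's adjusted p was 0.0763; without db/m 1 the list alone gave 8, without db/db 3 4, without db/db 1 or db/m 2 1 and without db/db 2 or db/m 3 0. The list did not pass camera without db/m 2 (adjusted p = 0.0516) or without db/m 3 (0.132). Nuclear-encoded oxidative phosphorylation genes lay 0.31 above all rows (camera adjusted p = 0.0218; 0.992 as the adjusted p with an estimated correlation), with 0 of 51 members past the threshold over all rows or over the list alone and 0 at an unadjusted p under 0.05 (limma; fry adjusted p = 0.683). The list did not pass without db/db 1, db/db 2 or db/m 3 (camera adjusted p 0.174, 0.487 and 0.233). Cox5b measured 169 ± 43 against 88.7 ± 40.2 and Cox6c 230 ± 54 against 130 ± 50.

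**Figure D3:**
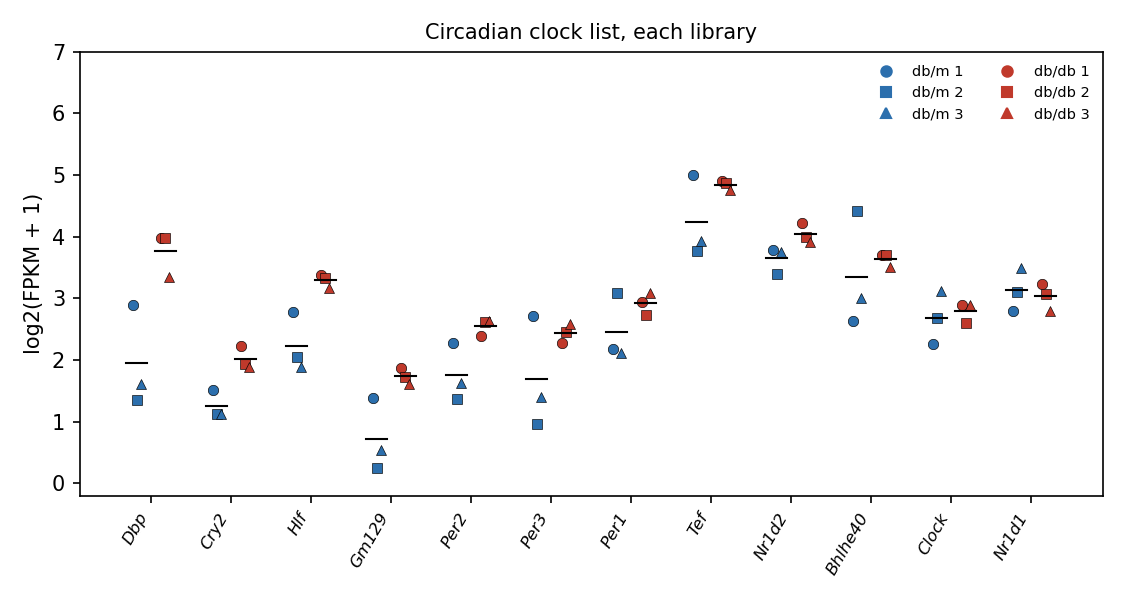
Each point is 1 library (blue db/m, red db/db, marker shape the replicate number) for 12 of the 13 tested members of the circadian clock list, ordered by p; the vertical axis is log2(FPKM + 1) and black lines are group means. Dbp, Cry2, Hlf, Gm129 and Per2 have all db/db libraries above all db/m libraries, and for Dbp db/m 1 at FPKM 6.42 lies nearer to db/db than the other db/m libraries.

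The 6 lists called lower all lost the call with an estimated correlation (adjusted p = 0.992 for each). Their medians relative to all rows were -0.25 for proximal tubule markers (camera adjusted p = 3.9e-05), -0.034 for fatty acid oxidation and PPAR targets (0.0223), -0.33 for endoplasmic reticulum stress (3.9e-05), -0.23 for complement (0.0065), -0.29 for immediate early genes (1.13e-05) and -0.66 for heat shock genes (5.1e-08). The immediate early and heat shock lists, like the ribosomal protein list, had been fixed as checks of quality and not as pathways. With median-ratio scaling the fatty acid and complement lists did not pass (camera adjusted p 0.0763 and 0.142). Without db/m 2 the heat shock list alone of these 6 passed, with camera adjusted p for the others of 0.107 (proximal tubule), 0.4 (fatty acid), 0.156 (endoplasmic reticulum stress) and 0.374 (complement and immediate early), and without db/db 3 the fatty acid list did not pass (0.452). As deposited, the medians of the proximal tubule, fatty acid, complement and immediate early lists were above 0 (0.037, 0.25, 0.055 and 0.0024), and their means were -0.14, 0.15, 0.026 and -0.13, so the median of these 4 lay lower relative to other rows and not as deposited. Of 21 proximal tubule markers, Slc7a13, an amino acid transporter, passed over the list alone (7.53 ± 3.90 in db/db, 53.5 ± 31.2 in db/m) but in none of the 6 fits with a library left out, while Kap measured 1029 ± 567 and 5332 ± 3781, and Pck1, of gluconeogenesis, 1228 ± 304 and 673 ± 192. Cd36, a fatty acid transporter, measured 5.13 ± 3.17 and 27.6 ± 19.7. Of the complement list, C4a and C3 went opposite ways, 0.519 ± 0.183 against 2.73 ± 1.89 and 12.4 ± 5.9 against 4.2 ± 3.0. The biotype matched to the C4a row was transcribed pseudogene. Egr1 measured 2.12 ± 0.87 and 5.83 ± 4.11.

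As deposited, none of the 12 heat shock genes passed over the list alone, and 0 had an unadjusted p under 0.05 (limma); with quantile normalization 2 passed, Hsph1 and Hspd1, both lower in db/db. Hspa1a, an inducible chaperone, was at 3.21, 3.63 and 2.90 in db/db, at 103 and 39.6 in db/m 2 and db/m 3 and at 0.626 in db/m 1. Without db/m 1 the list alone gave 10 heat shock genes and 4 endoplasmic reticulum stress genes (Xbp1, Asns, Sdf2l1 and Creld2), all lower in db/db, and with median-ratio scaling as well it gave 10 and 11. Of the genes named in this paragraph, Hspd1, Xbp1, Sdf2l1 and Creld2 were not chosen by the naming rule but because they passed in these settings.

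The other 20 lists did not pass as deposited (camera adjusted p from 0.104 to 0.984), and of their 349 tested entries 28 higher and 3 lower had an unadjusted p under 0.05. The red cell, extracellular matrix, lipid synthesis, angiogenic, renin-angiotensin and cell cycle lists had medians above that of all rows while camera's direction was down. With median-ratio scaling the glycolysis, NRF2, interferon and ribosomal protein lists passed at the preset correlation, all higher (camera adjusted p 0.00704, 0.00576, 0.0471 and 0.0209), and all 4 lost the call (adjusted p = 0.912 with an estimated correlation). Among antioxidant and NRF2 targets, Hmox1, the inducible heme oxygenase, passed over the list alone (57.3 ± 29.6 in db/db, 8.10 ± 4.70 in db/m) but not over all rows (adjusted p = 0.351), and over the list alone in only 1 of the 6 fits with a library left out (without db/db 3). Ppargc1a, a regulator of mitochondrial biogenesis, measured 8.91 ± 0.26 and 4.69 ± 1.20, with no overlap between the groups and an adjusted p of 0.502. A second Ppargc1a row at the same locus (NR_027710) was listed at 0 in db/db and at 3.05, 0.821 and 1.03 in db/m, and the log2 fold change of 0.82 became 0.44 summed over the rows, and 0.095 with median-ratio scaling as well. Extracellular matrix genes, often studied in diabetic glomeruli, had 1 of 22 members at an unadjusted p under 0.05, Mmp2 (3.44 ± 1.76 and 1.23 ± 0.75). Values without overlap between the groups were found in 18.5% of tested rows. For any 1 row, chance gives 10%. Because rows move together across libraries, the share for a given split can lie far from that by chance. The share was not computed for other splits, so an excess was not tested.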

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

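The alternatives that sum the rows of a symbol, and the one that leaves out db/m replicate 1 together with median-ratio scaling, were chosen after seeing the data. Of 22 alternatives, 13 left the count of 22 rows within 1.5 times. Weights per library gave a count of 717, with weights of 0.11, 0.57 and 4.94 for db/m 1, db/m 2 and db/m 3, so that db/m 3 held most of the db/m weight. The count was 11 with a pseudocount of 0.1, 6 with 0.01, 11 with a minimum mean of 5 (fewer rows tested), 14 without db/m replicate 1 under median-ratio scaling, and 4 to 28 with 1 library left out (8 without db/m replicate 1). Summed per symbol it was 21, with 15 shared. The count of 1 noncoding row became 0 with either pseudocount, with a minimum mean of 0.1 or 5, with median-ratio scaling, quantile normalization or TPM rescaling, without the variance trend, with the replicate block, and in both added settings with median-ratio scaling. It was 15 with weights per library and 0 to 1 with a library left out. Where 1 row passed with a library left out or without a minimum mean, that row was not Gm53. The 8 lists became 13 with weights per library, 0 with an estimated correlation and 0 with fry. The estimated correlation was added after seeing the data to each other scaling, each fit with a library left out and the replicate block, and gave 0 lists in every one. The cause was not tested except where named. For the 31 genes and rows named outside the lists, 494 of 649 results kept direction and side of the threshold, 132 lost a call, 7 gained one and 16 turned. None of the 15 genes past the threshold turned, which their choice without overlap between the groups left possible only with another scaling.

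The log2 fold changes that turned were all of rows that did not pass, and the cause was not tested. With weights per library they were -0.16 for Nphs1, -0.68 for Wt1 and -0.096 for Neat1. With median-ratio scaling they were -0.10 for Tug1 (NR_002321) and -0.37 for Neat1, with quantile normalization -0.090 and -0.33, and with TPM rescaling -0.043 for Neat1. Summed per symbol Tug1 was 0.16, which turned the sign of its shorter row only (-0.10 as deposited). With median-ratio scaling as well Tug1 was -0.20, which turned that of the longer row (0.25 as deposited), and Neat1 was -0.37. With db/m replicate 1 left out and median-ratio scaling they were -0.023 for Wt1, -0.017 for Tug1 and -0.13 for Neat1. With 1 library left out Neat1 ranged from -0.061 to 0.097.

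No pairing of the samples by replicate number was seen, though so few libraries cannot exclude one. Same-numbered libraries deviated from their group means with correlations of -0.21, 0.15 and 0.14, and other pairs with -0.36 to 0.26. Not every library correlated best with its own number. With the replicate block 24 rows passed, 18 of them shared, and 8 lists, of which the oxidative phosphorylation list lost its call (camera adjusted p = 0.437) and the mesangial list gained one (0.00533; adjusted p = 0.987 with an estimated correlation). Lepr gave -0.20 with adjusted p of 0.619 and 0.661 at a minimum mean of 0.1 and without one; other alternatives hold no test of it. Depth is unknown and limits low rows most.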

Other observations

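The splits of the samples into other groups, for all rows, and the tests of scaling, cell mix, proximal tubule share and both clock explanations were chosen after the result they bear on was seen, as were the added gene lists and the sums per symbol. Further genes outside the report's naming rule also separated the groups, and are given as values. With median-ratio scaling, rows of Cyp2j13, Acsm3, Hsd11b1, Atp11a, Ugt8a and Il34 passed, all lower in db/db (adjusted p from 0.0339 to 0.0473, limma; as deposited none passed, with 0.129 for Acsm3 to 0.397 for Il34). As deposited, Cyp2j13 measured 9.69 ± 2.20 in db/db and 41.3 ± 15.1 in db/m, and Acsm3 3.81 ± 1.76 and 31.4 ± 16.0 (SD, n = 3 each). Summed per symbol, Gsta1 and Gm3776, members of the same glutathione S-transferase cluster as Gsta2, passed at 9.08 ± 5.92 against 0.240 ± 0.156 and 5.76 ± 3.23 against 0.0706 ± 0.0808 (adjusted p 0.0313 and 0.0296, limma; 0.0574 for both as rows).

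A list of 20 genes with higher expression in the male than in the female kidney was written after the leading rows had been seen; 8 of its genes had been seen to be lower in db/db (Slco1a1, Slc7a13, Kap and others), 12 had not, and 4 are also proximal tubule markers. Of the 12, 11 had a lower mean in db/db, and 11 with median-ratio scaling. Among them were Cyp7b1 (2.52 ± 1.22 against 18.2 ± 17.9), Odc1 (24.1 ± 4.4 against 46.4 ± 19.1) and Cyp4b1 (318 ± 110 against 598 ± 334, SD, n = 3 each). Cyp2d9 went the other way (80.8 ± 43.6 against 41.0 ± 27.8). Only Cyp7b1, Odc1 and Mep1b had no overlap between the groups. None of the 12 passed in the fit without a minimum mean (adjusted p 0.644 to 0.907, limma). Their mean log2(FPKM + 1) overlapped as well, at 5.1, 4.9 and 4.2 in db/db and 4.4, 6.2 and 5.2 in db/m. A smaller share of proximal tubule in the db/db libraries is argued against as the whole of the difference in these 12 genes. That holds only if a smaller share lowers all proximal tubule genes alike, which was not tested. The median log2 fold change of the 17 other proximal tubule markers exceeded that of the 12 unseen genes by 0.53 (0.51 with median-ratio scaling). The difference of the list means differed between the groups by 0.66 and varied within a group by at most 0.39. Lower male-biased expression within the tubule stays open as a hypothesis: the median of the 12 unseen genes lay -0.53 from that of those markers, only just past the bound of -0.5, and the difference of the list means had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. Sex hormones were not measured, and a direct effect of diabetes or of the genotype was not tested.

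The 2 arms of the clock loop went opposite ways in part. The median log2 fold change of 10 genes of the Dbp and Per arm was 0.68, with 9 higher in db/db, and that of 3 genes of the Arntl arm was -0.12, with 2 lower, a difference of 0.80. The 2 lower genes were near the floor, under the minimum mean for testing: Arntl (0.232 ± 0.095 in db/db, 1.15 ± 0.85 in db/m) and Npas2 (0.285 ± 0.132 and 0.416 ± 0.314, SD, n = 3 each). Arntl in db/m 1, at 0.235, lay within the range of db/db. In the other arm Bhlhe41 was also under that minimum. A shift of clock phase may underlie this; with median-ratio scaling all 3 genes of the Arntl arm were lower, Clock included (-0.21, against 0.11 as deposited), but Nr1d1 went against its arm in both, so the shift stays undecided. The labels give a collection time for 0 of the 6 libraries, so the time of day at which each mouse was killed cannot be told apart from diabetes. The library of db/m 1 was nearer to db/db than the other db/m libraries for Dbp and, at 5.55, above all 3 db/db libraries for Per3.

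The library of db/m replicate 1 lay apart, and several explanations were weighed. Scaling by a few abundant short rows does not account for all of it: its mean Spearman correlation with the other libraries over protein-coding rows, which no scaling changes, was 0.823, against 0.881 to 0.903 for the others. Another mix of cell types is argued against as what singles it out: its cell type lists moved apart by 3.38 log2 units, less than in db/db 2 (4.37) and db/m 2 (3.46), and by 0.655 without the red cell list, where 4 other libraries had more. A length-dependent difference in RNA may contribute: its deviation from the others correlated with transcript length at a Spearman rho of 0.296 across 11169 protein-coding rows, against -0.265 to 0.139 in the others, a narrow margin in size, and genes are not independent replicates. No other biological explanation was tested.

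The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 22 rows and the highest other split 7, and 1 of the 10 splits, the real one itself, gave as many. For noncoding rows the real split gave 1 and the highest other also 1, with 4 splits, the real one included, giving as many. For lists the real split gave 8 and the highest other 17, with 9 splits, the real one included, giving as many, so at the preset correlation camera called more lists for most groupings that mix the genotypes. Rows at 0 in all libraries of 1 group and at least 1 in all of the other numbered 5 (db/db at 0) and 8 (db/m at 0), against 0 to 10, median 2, for the 18 other sets of 3 libraries.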
